A study of Caenorhabditis elegans with 39 samples.

How the data were processed

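Small RNA sequencing measured microRNAs (miRNAs), short RNAs that repress target mRNAs, in total RNA of whole Caenorhabditis elegans. The 39 libraries cover 3 genotypes, named in the labels N2 (the standard wild type strain), Alg1A and Alg1E, with 13 libraries each. Each genotype has 1 library for every hour from 18 to 30 h at 25 degrees after plating of synchronized first-stage (L1) larvae. The labels call Alg1A and Alg1E mutants of ALG-1 and do not spell out the letters. They give each library a genotype and an hour, and no replicate number, culture or batch, so libraries of the same hour were matched only through the hour.

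The libraries were made with the QIAseq miRNA Library Kit, per the labels' protocols. Per the submitters' processing notes, cutadapt 2.3, Bowtie 1.2.2, SAMtools 1.9 and HTSeq were used with the genome build ce11. The settings of trimming, mapping and counting, the use of strand, the annotation version and the use of the kit's unique molecular identifiers are not given in the sources used here. If reads were not collapsed by those identifiers, PCR copies count as reads, and near-identical miRNAs share reads in a way that depends on the mapping. miR-44-3p and miR-45-3p kept a nearly fixed ratio of 2.88, so their separate values are uncertain.

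The deposited table holds whole-number counts of reads per mature miRNA made by the authors, with no normalization. It has 437 miRNA entries, of which 33 had no read, and 5 HTSeq summary entries that name no gene. Reads without a feature made up 37.2% ± 9.48 of the reads in N2, 35.3% ± 9.64 in Alg1A and 49.5% ± 11.4 in Alg1E (SD, n = 13 each). Ambiguous reads took at most 0.111% of any library, and the other summary entries were at 0. The summary entries were left out of library sizes and tests. The miRNA reads per library ranged from 1751599 to 4479656 in N2, from 1245377 to 4472517 in Alg1A and from 1146950 to 4668890 in Alg1E. Levels are given as counts-per-million (CPM) after TMM. A level of 10 CPM therefore rests on more than 10 reads in each library.

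edgeR 4.0.16 in R 4.3.3 tested the counts with its quasi-likelihood test. Library sizes were adjusted with TMM, the trimmed mean of M-values, which assumes that most miRNAs do not change. edgeR's filterByExpr kept 243 miRNAs. Genotypes were compared over all 39 libraries in a model of genotype plus hour as a factor. Change with time was tested within a genotype with a natural spline in hours with 3 degrees of freedom, and a difference in time course with the interaction of genotype and spline. Directions over time come from the fitted value at 30 h minus that at 18 h. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05.

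A hairpin precursor gives a 5p and a 3p arm. For each of the 190 hairpins listed with both, the arm with fewer reads over all 39 libraries was called minor and the other major. Both arms passed the filter for 96 hairpins. limma 3.58.1 tested the log2 ratio of minor to major arm (prior count 0.5) for 94 hairpins with a mean of at least 10 reads per arm. The share of reads in minor arms was compared by permutation tests of 100000 resamples. Age was estimated by placing each library, in steps of 0.1 h, on the N2 curves of the miRNAs that changed with time in N2, with each N2 library placed on curves fitted without it. The offsets were tested with an exact sign-flip test over the 13 hours.

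The comparisons, the filters, the lists and most alternatives were fixed before the data were examined. Named miRNAs follow a rule. In each genotype comparison it takes the 8 largest rises and falls among those past the threshold with a mean of at least 10 CPM and the same direction at 10 or more of 13 hours. Over time it takes the 8 largest rises and falls with at least 10 CPM, and between time courses the 8 smallest p-values. lin-4, let-7, mir-48, mir-84, mir-241, mir-237, mir-35 to mir-42 and the 5 miRNAs with most reads are always given. Lists were 16 seed families or groups of related miRNAs, mirtrons, markers of neurons, muscle and intestine, miRNAs with known roles in lifespan or stress, and the minor arms. The 14 lists with at least 3 tested members were tested with camera in limma on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera compares a list with all other miRNAs, so it can call a list that did not move when others did.

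The scripts were tested on simulated counts. For the comparison of Alg1E with N2, with 100 of 243 miRNAs changed, 50 of 50 changes of 2-fold and 34 of 50 of 1.5-fold were recovered, and 5 of 143 unchanged miRNAs were called. In a first simulation of the time course of Alg1E against N2, in which 60 of 243 miRNAs all rose 4-fold, a midpoint 2 h later was called for 0% of them and 15 of 183 unchanged miRNAs were called as changing in N2. The age placement then gave an offset of -1.6 h where -2 had been set and -1 where 0 had been set. A further simulation was made after that outcome, with 30 of the 60 rising and 30 falling 16-fold. It called 58.3% of the later midpoints. Placement was simulated separately, with all libraries drawn from the N2 curves and no level differences between genotypes apart from the shift. Over 50 draws it gave -1.8 h for -2 and 0 h for 0, with 0 of 50 draws under an exact sign-flip p of 0.05. Camera gave p = 0.000787 for major arms left unchanged while other arms rose, which is a call on an unmoved list.

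Alternatives were other scalings (DESeq2 1.42.0 size factors, written RLE, total counts, and TMM factors without minor arms), other filters, DESeq2 and limma-voom, other time terms, subsets of hours, each hour left out in turn, and other list tests. TMM from major arms takes its factors from major arms and from miRNAs of hairpins not listed with both arms, and TMM from paired major arms from major arms of hairpins listed with both. Both of these, the share of reads without a feature as a covariate, the shift of the Alg1E hours, the scalings of the let-7-5p crossing, the centred and major-arm age placements and the omission of the Alg1A libraries of 18 and 19 h were chosen after the data had been seen. Coordinates come from the annotation of WBcel235, the assembly that is also called ce11. Of 247 hairpin names, 240 matched it. Host genes were looked up among protein-coding genes only. Of the 240 hairpins, 138 overlapped no such gene and are called intergenic, 94 lay in an intron and 8 overlapped an exon. Confidence intervals cover counting error only.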

Results

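The series measured miRNA levels in larvae of 3 C. elegans genotypes over the same 13 hours of development. N2 is the standard wild type. Alg1A and Alg1E are mutants of alg-1, which encodes an Argonaute, a protein that binds a miRNA and brings it to target mRNAs. The gene lies on chromosome X from 13949110 to 13956261 (+ strand, WBcel235), and the series title concerns phosphorylation of its product and miRNA binding. There was 1 library per genotype and hour, from 18 to 30 h after plating. The median library held 3529334 miRNA reads in N2, 2892326 in Alg1A and 2105603 in Alg1E, and 243 miRNAs were tested. Reads without a feature took 49.5% in Alg1E against 37.2% in N2, a difference of 12.4 points (two-sided permutation p = 0.00642, n = 13 each). The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between hourly libraries, which may be technical. The residuals of neighbouring hours were correlated in the comparison of Alg1E with N2 (median lag-1 correlation 0.34 against -0.08 for independent hours), which makes its p-values too small. Means carry the SD over the 13 hours, development included.

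The comparison of Alg1E with N2 asked which miRNAs differ in this alg-1 mutant. The largest increases were all minor arms, the strands of a hairpin that usually give few reads. miR-52-3p, from the hairpin whose other arm is among the most abundant miRNAs, was at 5463 ± 1765 CPM in Alg1E against 448 ± 94.7 in N2, 11.9-fold higher. miR-237-3p was 11.1-fold higher, from 42.9 ± 21.3 to 457 ± 246 CPM, and miR-56-5p 10.9-fold higher, from 563 ± 105 to 6183 ± 1589 CPM. miR-70-3p, among the 5 miRNAs with most reads, was lower, at 18248 ± 4563 CPM against 85036 ± 15925. miR-241-5p, a let-7 relative that acts in the timing of larval stages, was lower too, at 360 ± 107 CPM against 1434 ± 406.

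edgeR called 182 of 243 miRNAs between Alg1E and N2, with 88 higher and 94 lower, and 62 of the higher and 37 of the lower differed by more than 2-fold. The log2 differences were 3.57 (SE 0.141) for miR-52-3p, 3.48 (SE 0.308) for miR-237-3p and 3.45 (SE 0.123) for miR-56-5p, with edgeR adjusted p = 1.24e-19, 2.01e-11 and 1.30e-20, each higher at 13 of 13 hours. miR-87-5p (3.36), miR-72-3p (3.30), miR-73-5p (3.22), miR-60-5p (3.19) and miR-235-5p (3.17) complete the 8 largest increases. The lowest were miR-799 at -3.49, miR-247-3p at -2.23, miR-70-3p at -2.22 (edgeR adjusted p = 1.12e-15, lower at 13 of 13 hours) and miR-241-5p at -1.99 (edgeR adjusted p = 2.02e-13, lower at 13 of 13 hours). They were followed by miR-357-3p (-1.80), miR-788-5p (-1.78), miR-5551-5p (-1.73) and miR-8196b-3p (-1.68). miR-357-3p ranged from -2.21 to -0.17 over 32 alternative settings and was not called in 2 of them. It rose during these hours and reached the midpoint of its rise 2.29 h later in Alg1E, so level and timing cannot be told apart in its decrease. Of the miRNAs with most reads, miR-52-5p (-0.61) and miR-81-3p (-0.49) were also called lower, while miR-58a-3p (-0.03) and the muscle miRNA miR-1-3p (0.33, edgeR adjusted p = 0.0569) were not called. The median over all miRNAs moved by -0.12 log2 with RLE factors, by 0.27 with total counts, by 0.44 with TMM from major arms and by 0.53 with TMM from paired major arms (hairpins listed with both arms). The split of 88 higher to 94 lower became 114 to 65, 125 to 52 and 129 to 49 with the last 3.

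The mir-52 hairpin is intergenic on chromosome IV from 14034008 to 14034107 (+ strand). The mir-56 hairpin lies on X from 13144691 to 13144787 (- strand), in an intron of F09A5.3 on the opposite strand. mir-70 lies on V from 6665536 to 6665635 (- strand) in an intron of pmp-5, on the same strand. mir-241 is intergenic on V from 14366188 to 14366283 (- strand), near mir-48.

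The heterochronic miRNAs, which time the larval stages, were lower in Alg1E for 6 of 6 members over all miRNAs and 6 adjusted over the list alone, with a median of -0.51 that became -0.07 with TMM from major arms and 0.01 with TMM from paired major arms. Beside miR-241-5p, these were let-7-5p (-0.98), which acts late in larval development, miR-237-5p (-0.58), miR-84-5p (-0.45), lin-4-5p (-0.42), the founding member of the class, and miR-48-5p (-0.38). With TMM from major arms, 1 of the 6 was called, and lin-4-5p (0.02) and miR-48-5p (0.06) lay above 0, as did miR-84-5p (0.08) with TMM from paired major arms. With estimated age in place of hour, let-7-5p differed by -0.14 (edgeR adjusted p = 0.563), but that age rests in part on let-7-5p itself, so part of this loss is built in. Against other miRNAs the list as a whole was not called (camera adjusted p = 0.162, unadjusted p = 0.0346, and adjusted p = 0.277 with an estimated correlation). The list test fry, which does not compare a list with other miRNAs, called it lower with TMM (fry adjusted p = 3.23e-12).

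Among seed families in Alg1E against N2, the let-7 family had 7 of 8 members lower and 1 higher (miR-793, 0.90), the mir-64 family 5 of 5 lower, the mir-35 family, which embryos need, 5 of 8, the mir-58 family, related to bantam, 3 of 4, and the mir-51 family 3 of 6. Both members of the lin-4, mir-75 and mir-46 families were lower. The mir-232 and mir-87 families each had 1 of 2 lower, the mir-238 family 1 of 3, the mir-44 family 1 of 4, and the mir-72 family 2 of 3 lower and 1 higher. The mir-2 family had 1 of 4 higher and 1 lower, and the mir-251 family 1 of 2 higher. In the mir-35 family, miR-40-3p (-1.09), miR-36-3p (-0.76), miR-35-3p (-0.43), miR-37-3p (-0.43) and miR-38-3p (-0.37) were called, and miR-41-3p (-0.60), miR-39-3p (-0.15) and miR-42-3p (0.04) were not. Adjusted over the list alone, the mir-51 family had 2 lower, muscle 1 higher and the minor arms 5 lower, and the other counts were equal to those over all miRNAs.

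Family medians against N2 were below 0 under each scaling for the let-7 (-0.56), mir-58 (-0.64), mir-64 (-0.67), mir-75, mir-46 and mir-232 families and for the intestinal miR-60-3p (-0.71, called lower). The medians of the mir-35 (0.01), mir-51 (0.08), mir-2 (0.35), mir-72 (0.18), mir-87 (0.21) and mir-238 (0.21) families, mirtrons (0.41) and lifespan miRNAs (0.21) turned above 0 with TMM from major arms, in part already with total counts. That of the lin-4 family (-0.06 with TMM from major arms) turned above 0 with TMM from paired major arms (0.03), and that of the mir-44 family turned to -0.02 with RLE. Of 4 miRNAs listed as mirtrons, which are spliced introns that bypass the Drosha enzyme, miR-1018 was higher (0.47) and miR-1019-5p lower (-2.12). The annotation places mir-1018 outside protein-coding genes, on X from 1879458 to 1879513 (+ strand). Other genes were not searched, so its place in that list stays uncertain. The neuron markers had lsy-6-3p, which sets left and right taste neuron identity, higher (0.50) and miR-124-3p, a sensory neuron miRNA, lower (-0.44) among 3. The lifespan list had 3 of 7 lower, miR-246-3p (-1.32), miR-228-5p (-0.82) and miR-238-3p (-0.43). miR-246-3p reached the midpoint of its rise 1.93 h later in Alg1E, so level and timing cannot be told apart in its decrease. The median and mean differed in sign for the mir-2 family (-0.10 and 0.07) and the mir-44 family (0.09 and -0.48). Of 14 lists tested with camera, 1 was called in each genotype comparison, the minor arms, with either correlation.

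Minor arms were compared with major arms because they made up the largest differences. Minor arms held 8.15% ± 0.585 of the reads of 96 hairpins in Alg1E, 1.95% ± 0.181 in Alg1A and 1.60% ± 0.149 in N2 (SD, n = 13 each). The mean share in Alg1E was 5.09 times that in N2 and 4.19 times that in Alg1A, and the share was higher at 13 of 13 hours in both comparisons (two-sided permutation p = 1e-05 for both, the smallest that 100000 resamples can give). The mean share in Alg1A was 1.21 times that in N2 and higher at 12 of 13 hours (two-sided permutation p = 3e-05). Between Alg1E and N2, 73 of 96 minor arms were called higher and 4 lower (median 1.66, camera adjusted p = 1.74e-28, and adjusted p = 6.20e-10 with an estimated correlation). Of the 96 major arms, 5 were higher and 65 lower (median -0.48), a split that became 25 higher and 27 lower with TMM from major arms (median -0.04) and 28 and 25 with TMM from paired major arms (median 0.04).

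**Figure D1:**
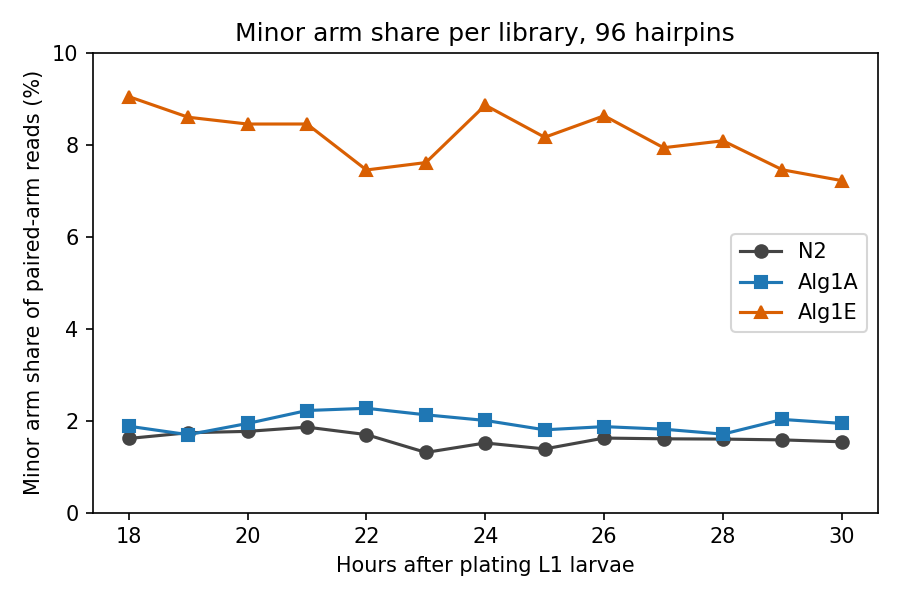
Minor arm share of the reads of 96 hairpins (%) in each library against hours after plating, with 1 point per library joined within N2, Alg1A and Alg1E. The 13 Alg1E libraries lie above all libraries of the other genotypes, with means of 8.15% in Alg1E, 1.95% in Alg1A and 1.60% in N2.

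The ratio of minor to major arm within a hairpin does not depend on scaling between libraries. Its median log2 change was 2.05 in Alg1E against N2, 4.14-fold, and limma called it higher for 81 and lower for 2 of 94 hairpins at an adjusted p under 0.05. miR-71, whose loss shortens lifespan, had a 3p arm at 30.6% of its 5p arm in N2 and 106% in Alg1E. miR-71-3p was at 19926 ± 4440 CPM in Alg1E against 5796 ± 1555 in N2 (log2 1.80), while miR-71-5p was not called (0.03). The minor arm also exceeded the major arm in Alg1E for miR-235 (104.3% against 10.1% in N2) and miR-240 (147% against 32.0%), hairpins chosen after their values were seen.

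**Figure D2:**
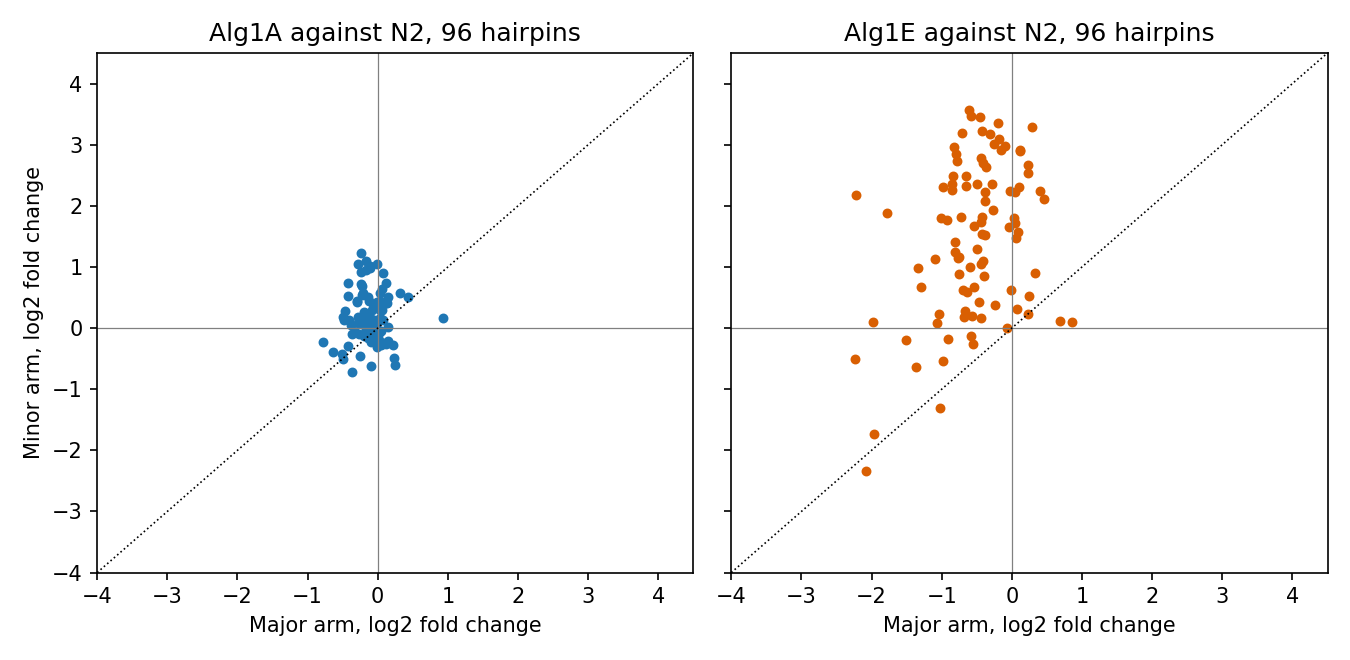
Log2 fold change of the minor arm (vertical) against that of the major arm (horizontal) for 96 hairpins, 1 point per hairpin, for Alg1A (left) and Alg1E (right) against N2, with equal change on the dotted diagonal. In Alg1E the medians were 1.66 for minor and -0.48 for major arms, the latter -0.04 with TMM from major arms and 0.04 with TMM from paired major arms, and in Alg1A they were 0.15 and -0.11.

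The comparison of Alg1A with N2 asked the same of the other mutant, and far fewer miRNAs differed. Most of the largest increases were again minor arms. miR-46-5p was at 1238 ± 164 CPM in Alg1A against 527 ± 50.3 in N2, and miR-63-5p at 476 ± 61.2 against 230 ± 28.2. miR-230-5p was at 502 ± 94.9 CPM against 239 ± 25.8, and miR-83-5p at 86.3 ± 32.5 against 38.9 ± 7.32. The largest called decrease was in miR-240-3p, at 110 ± 94.3 CPM against 174 ± 144.

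edgeR called 26 of 243 miRNAs between Alg1A and N2, with 21 higher and 5 lower, and 6 higher by more than 2-fold. The split was 31 to 3 with total counts and 30 to 2 with TMM from paired major arms, where the median of all miRNAs moved by 0.11. miR-46-5p had a log2 difference of 1.23 (SE 0.0934, edgeR adjusted p = 1.87e-11, higher at 13 of 13 hours), from a hairpin on III from 13660515 to 13660611 (+ strand, intergenic). It was followed by miR-83-5p (1.09), miR-63-5p (1.05), miR-230-5p (1.04), miR-47-5p (0.96), miR-791-5p (0.92), miR-65-3p (0.92) and miR-66-3p (0.91). The 5 lower were miR-240-3p at -0.64 (edgeR adjusted p = 0.0122, lower at 11 of 13 hours), miR-1829c-3p (-0.60), miR-1829a-3p (-0.47), miR-786-3p (-0.42) and miR-787-3p (-0.36). Of 32 alternative settings, 18 did not call miR-1829c-3p, 13 miR-786-3p, 7 miR-240-3p, 5 miR-787-3p and 3 miR-1829a-3p. miR-240-3p reached the midpoint of its rise 1.28 h later in Alg1A, so level and timing cannot be told apart in its decrease. Of 96 minor arms, 16 were higher and 1 lower (20 and 2 adjusted over the list alone), with camera adjusted p = 3.00e-06 (adjusted p = 0.00147 with an estimated correlation). The ratio of minor to major arm was 1.22-fold higher at the median, with 19 of 94 hairpins called higher and 1 lower by limma. Of these 16 minor arms, 13 were 5p arms, against 48 of the 80 other minor arms (Fisher's exact two-sided p = 0.156).

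**Figure D3:**
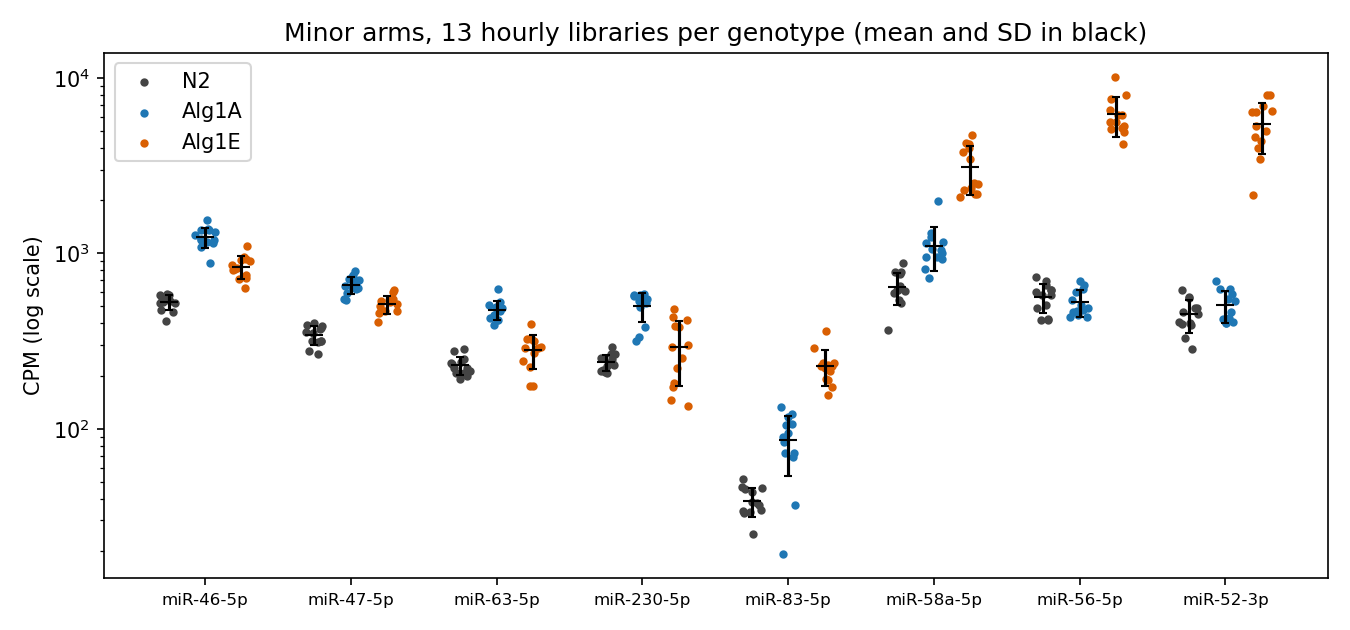
Levels in CPM on a log scale of 8 minor arms in N2, Alg1A and Alg1E, with 1 point per library (13 each) and the mean and SD in black. miR-46-5p, miR-47-5p, miR-63-5p and miR-230-5p lie highest in Alg1A (1238 CPM for miR-46-5p), and miR-83-5p, miR-58a-5p, miR-56-5p and miR-52-3p in Alg1E (6183 CPM for miR-56-5p). With TMM from major arms, miR-47-5p lay above 0 in Alg1E against Alg1A (0.01).

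Of the heterochronic miRNAs, 0 of 6 were called between Alg1A and N2 by edgeR over all miRNAs or adjusted over the list alone, 0 had an unadjusted p under 0.05, and let-7-5p differed by -0.50 (edgeR adjusted p = 0.206, n = 13 hours). The same counts held for 8 members of the mir-35 family. Of the 5 miRNAs with most reads, the one nearest to a call was miR-81-3p (-0.27, lower at 12 of 13 hours, edgeR adjusted p = 0.0664). Over all miRNAs, the let-7 family had 1 of 8 higher (miR-1821-3p, 0.50), mirtrons 1 of 4 (miR-1019-5p, 0.53) and neuron markers 1 of 3 (miR-791-5p). Adjusted over the list alone, the mir-44 and mir-64 families each had 2 lower, the mir-58 and mir-232 families and intestine each 1 lower, and neuron markers 1 higher and 1 lower. The mirtron median and mean differed in sign (-0.13 and 0.03), and so did camera for the mir-2 family, with a median of 0.00 and a downward direction. Called miRNAs numbered 54 without the Alg1A libraries of 18 and 19 h, 29 higher and 25 lower, with 26 shared. Those libraries held the muscle miRNA miR-1-3p at 36473 and 17158 CPM, against 66519 to 125956 CPM in N2.

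The comparison of Alg1E with Alg1A tested the difference between the mutants directly. miR-87-5p was 12.4-fold higher in Alg1E, at 693 ± 218 CPM against 58.4 ± 27.7, and miR-56-5p 11.7-fold higher, at 6183 ± 1589 against 526 ± 91.5. miR-70-3p was lower, at 18248 ± 4563 CPM against 93207 ± 17268, and so was the mirtron miR-1019-5p, at 3.52 ± 0.947 against 21.8 ± 4.65. miR-230-5p (-0.84), miR-63-5p (-0.77) and miR-46-5p (-0.56) were called lower in Alg1E than in Alg1A. With TMM from major arms these were -0.47, -0.40 and -0.19, and miR-46-5p was not called (edgeR adjusted p = 0.0855). As a ratio to the major arm, limma called miR-63-5p lower (-0.39, adjusted p = 0.0298) but not miR-230-5p (-0.28, adjusted p = 0.0771) or miR-46-5p (-0.26, adjusted p = 0.141).

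edgeR called 190 of 243 miRNAs between Alg1E and Alg1A, with 95 higher and 95 lower. The split became 115 to 52 with TMM from major arms, where the median of all miRNAs moved by 0.37, and 119 to 49 with TMM from paired major arms, where it moved by 0.42. That median moved by 0.18 with total counts and -0.10 with RLE. The log2 differences were 3.63 for miR-87-5p (edgeR adjusted p = 1.69e-16, higher at 13 of 13 hours), 3.61 for miR-237-3p, 3.55 for miR-56-5p, 3.52 for miR-72-3p, 3.40 for miR-52-3p, 3.14 for miR-235-5p, 3.08 for miR-73-5p and 3.08 for miR-55-5p. The largest decreases were miR-799 (-3.53), miR-1019-5p (-2.65), miR-70-3p (-2.35), miR-247-3p (-2.29), miR-241-5p (-1.98), miR-8196b-3p (-1.96), miR-5551-5p (-1.67) and miR-1829a-5p (-1.58). Minor arms were higher for 71 of 96 and lower for 11 (6 with TMM from major arms), over all miRNAs and adjusted over the list alone (camera adjusted p = 1.16e-19, and adjusted p = 6.01e-08 with an estimated correlation). The arm ratio was 3.42-fold higher at the median, with limma calling 77 of 94 hairpins higher and 4 lower. miR-1-3p was higher in Alg1E than in Alg1A (0.49, edgeR adjusted p = 0.00572, at 12 of 13 hours). The heterochronic list had 5 of 6 lower and the let-7 family 6 of 8 lower and 1 higher (1 and 2 lower with TMM from major arms), with medians of -0.44 and -0.47 that stayed below 0 under each scaling. The medians of the mir-35 (0.10), mir-51 (0.35), mir-2 (0.28), mir-87 (0.14) and mir-238 (0.24) families and of lifespan miRNAs (0.24) turned above 0 with TMM from major arms, in part already with total counts, and those of the lin-4 (0.02), mir-58 (0.01), mir-46 (0.05) and mir-72 (0.02) families with TMM from paired major arms, while that of mirtrons turned to -0.01 with RLE. Adjusted over the list alone, the mir-87 family had 0 lower in place of 1 by edgeR (1 at an unadjusted p under 0.05), and all other counts were equal. The median and mean differed in sign for the mir-2 family (-0.10 and 0.07), the mir-44 family (0.44 and -0.22) and mirtrons (0.09 and -0.46), and the median and fry's direction for neuron markers (-0.57, upward).

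The change over time in each genotype was led by a small set of rising miRNAs. In N2, miR-85-3p rose from a mean of 8.90 ± 2.99 CPM at 18 to 20 h to 4950 ± 2224 CPM at 28 to 30 h, and let-7-5p from 541 to 17000 CPM. miR-246-3p, a miRNA with a role in lifespan, rose 38.8-fold to 388 CPM, miR-240-3p from 12.2 to 369 CPM and its cluster neighbour miR-786-3p from 53.2 to 1276 CPM. miR-85-3p also rose in Alg1A, from 11.9 to 3562 CPM, and in Alg1E, from 11.5 to 1511 CPM. let-7-5p reached 12340 CPM in Alg1A from 497, and 14309 CPM in Alg1E from 415.

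edgeR called 84 miRNAs as changing with time in N2 (47 rising and 37 falling), 111 in Alg1A (45 and 66) and 65 in Alg1E (37 and 28). With total counts these splits were 39 to 52 in N2, 67 to 48 in Alg1A and 29 to 37 in Alg1E, where the median of all miRNAs moved by -0.10, 0.38 and -0.27, and with RLE the split was 53 to 53 in Alg1A, where it moved by 0.21. let-7-5p was called over the 13 hours in N2 (edgeR adjusted p = 4.60e-05), Alg1A (6.57e-06) and Alg1E (8.94e-08). In N2 the rises also took in miR-5592-3p, miR-85-5p, let-7-3p and miR-5592-5p, which had 0 reads at 18 to 20 h and was at least 295-fold higher at 28 to 30 h (floor of 3 reads over those libraries). The falls were miR-235-5p, miR-1022-5p, miR-254-3p, miR-790-5p, miR-229-3p, miR-235-3p, miR-244-5p and miR-228-3p, with miR-229-3p going from 1539 to 682 CPM. In Alg1A, miR-59-3p rose from 273 to 9667 CPM, and miR-5592-3p, miR-786-3p, miR-59-5p, miR-5592-5p, miR-786-5p and miR-85-5p (0 reads at 18 to 20 h) rose too. Its falls were miR-235-5p, miR-124-5p, miR-790-5p, miR-74-5p, miR-1022-5p, miR-791-5p, miR-56-3p and miR-233-5p. In Alg1E, miR-59-5p, miR-246-3p, miR-240-3p, miR-5592-3p, miR-786-3p, miR-240-5p and miR-786-5p rose, and miR-244-3p, miR-35-5p, lin-4-3p, miR-237-3p, miR-37-5p, miR-251, miR-42-5p and miR-76-3p fell.

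Heterochronic miRNAs rose for 4 of 6 in N2 and in Alg1E with none falling, and for 3 of 6 in Alg1A with 2 falling. Adjusted over the list alone, 5 rose in N2, 4 in Alg1E and 3 in Alg1A. The mir-51 family fell for 6 of 6 in Alg1A (median -1.65, under each scaling), but for 0 of 6 by edgeR without the libraries of 18 and 19 h (median -0.31, 1 with an unadjusted p under 0.05). Without those libraries the Alg1A count was 71, of which 51 rose and 20 fell, with 51 shared with the full set. The mir-35 family in Alg1A likewise went from 1 rising and 4 falling of 8 to 6 rising and none falling by edgeR (7 with an unadjusted p under 0.05).

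**Figure D4:**
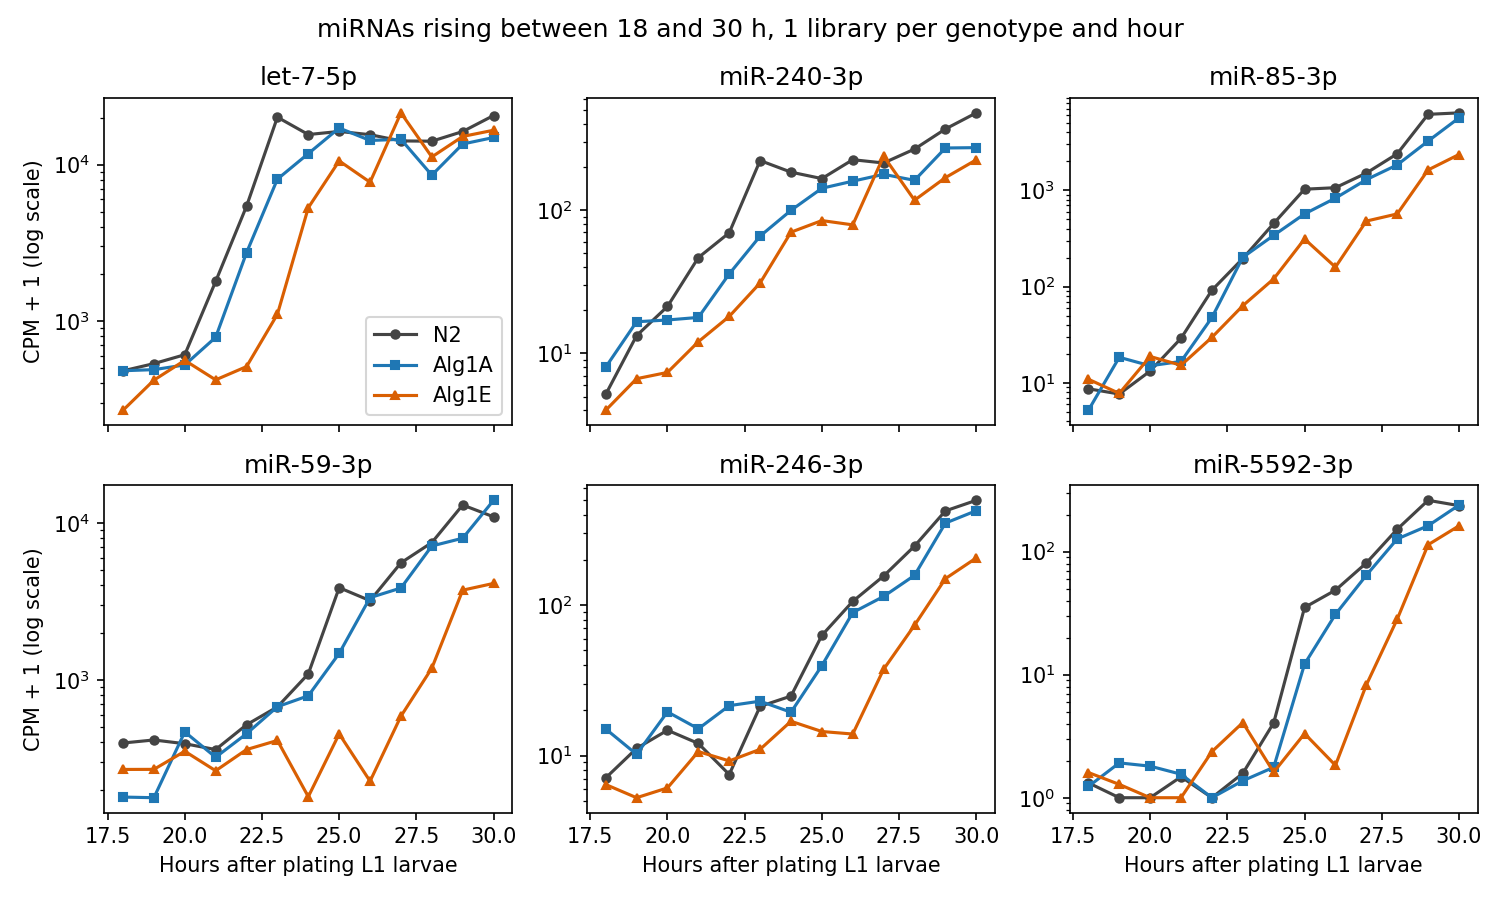
Levels of let-7-5p, miR-240-3p, miR-85-3p, miR-59-3p, miR-246-3p and miR-5592-3p in CPM plus 1 on a log scale against hours after plating, with 1 point per library joined within each genotype. let-7-5p passed 3144 CPM at 21.5 h in N2, 22.1 h in Alg1A and 23.7 h in Alg1E.

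The time courses of Alg1E and N2 were compared next, to ask whether levels change at the same hours. miR-59-3p, let-7-3p and miR-237-3p differed most clearly. let-7-3p, the minor arm of let-7, was highest at 30 h in N2, at 584 CPM, and at 25 h in Alg1E, at 3122 CPM. miR-237-3p, whose major arm is a lin-4 relative, was highest at 29 h in N2 and at 25 h in Alg1E. let-7-5p crossed 3144 CPM 2.16 h later in Alg1E than in N2 and 0.621 h later in Alg1A.

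edgeR called a different time course for 86 of 243 miRNAs in Alg1E against N2, with a difference in net change, Alg1E minus N2, above 0 for 40 and below 0 for 46 (28 and 57 with total counts). Over the 13 hours the edgeR adjusted p was 4.45e-05 for miR-59-3p, whose net changes were similar (4.89 log2 in N2 and 4.58 in Alg1E). It was 0.000597 for let-7-3p, with a fitted net change of 8.04 in N2 and 3.18 in Alg1E. The observed range of let-7-3p, as log2 of CPM plus 1, was 6.18 in N2 and 6.19 in Alg1E. The fitted 8.04 thus exceeds the observed change, and the ranges do not show a smaller change in Alg1E. miR-1022-5p, miR-76-3p, miR-244-3p, miR-251 and the mirtron miR-62 completed the 8 smallest. In Alg1A, edgeR called 6 miRNAs, all with a net change above that in N2, and they include miR-355-5p (1.40 against 0.14 log2 over 13 hours, edgeR adjusted p = 0.0262). That count was 0 by edgeR without the Alg1A libraries of 18 and 19 h, where 17 had an unadjusted p under 0.05, and with all libraries DESeq2 gave 14 and limma-voom 6.

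Placement of each library on the N2 curves of 84 miRNAs gave an estimated age. miR-85-3p, let-7-5p and miR-246-3p are among these curves. Alg1E libraries were placed 2 h earlier than the N2 libraries of the same hour at the median (offset -2 h, range -4.3 to 0.3, earlier at 11 of 13 hours, exact two-sided sign-flip p = 0.00146). By hour, the Alg1E offsets lay between -0.3 and 0.3 h at 18 to 20 h, where the start of the curves at 18 h limits how early a library can be placed, between -2.3 and -1.5 h at 21 to 24 h and between -4.3 and -3.8 h at 25 to 28 h, and were -1.3 h at 29 h and -0.4 h at 30 h. N2 libraries were placed within 1 h of their own hour. Placement compares levels, so level differences between genotypes can move it. Mean Alg1E offsets at 25 to 28 h were -4.08 h here, -2.88 h with major arms only and -1.90 h with each miRNA centred on its genotype mean. In the same order they were -2, -0.98 and -2.08 h at 21 to 24 h, and -0.85, -1.55 and -0.90 h at 29 to 30 h. The size of the Alg1E offset therefore depends on the placement. Alg1A libraries had a median offset of -0.7 h (range -1.4 to 0.2, earlier at 12 of 13 hours, exact two-sided sign-flip p = 0.000732). Neighbouring hours are not independent, so both sign-flip p-values are too small. Where an offset of 0 had been set, the first simulation gave -1 h. A separate one, with Alg1A drawn from the N2 curves themselves, gave a median of 0 h (range -0.2 to 0.3). It held no level differences between genotypes, so it cannot show that placement is free of bias where levels differ. The small offset of Alg1A is therefore uncertain. Of the major arms of 9 hairpins that rose strongly, mir-85 and let-7 among them, 9 reached their own midpoint later in Alg1E than in N2 (median 1.99 h, range 0.978 to 3.07), and 7 in Alg1A (median 0.615 h, range -0.257 to 1.28). The minor arms miR-240-5p and miR-85-5p reached theirs earlier in Alg1E than in N2, with lags of -1.17 and -1.06 h.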

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

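The tests of scaling by own midpoints, of exchanged hours, of a fixed later start, of moved hours in the same libraries and of offsets by hour were chosen only after the result was seen.

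Reads without a feature, which enter no comparison of miRNAs, took 49.5% in Alg1E, above the 37.2% in N2 and the 35.3% in Alg1A (permutation p = 0.00642 and 0.00262, n = 13 each). Single libraries ranged from 32.4% to 67.0% in Alg1E and from 25.7% to 54.1% in N2.

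The time courses of 86 miRNAs differed between Alg1E and N2 by edgeR's interaction test. Of 100 splits of the 26 libraries, the real one among them, 3 gave as many calls, with 107 as the highest other count. These splits mixed libraries of different hours and broke the correlation of neighbouring hours. They put the count past 0.05 only if the libraries are independent, and do not exclude chance otherwise. The smallest edgeR adjusted p-values over the 13 hours belonged to miR-59-3p (4.45e-05, net change 4.58 log2 in Alg1E and 4.89 in N2), let-7-3p (0.000597, 3.18 and 8.04), miR-1022-5p (0.000597, -0.44 and -1.66) and miR-237-3p (0.000776, -1.71 and 1.92). They were followed by miR-76-3p (0.000776, -1.39 and -0.69), miR-244-3p (0.00091, -2.99 and -0.12), miR-251 (0.00108, -1.60 and -0.33) and miR-62 (0.00109, -1.30 and -0.20). Net changes are fitted values, and the 8.04 of let-7-3p in N2 exceeds its observed range of 6.18 log2 (CPM plus 1).

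Strongly rising miRNAs such as let-7-5p and miR-59-3p rose later in Alg1E. Lower levels or a scaling equal at all hours would move a crossing of a fixed level but not the midpoint of a miRNA's own rise. That midpoint was later for the major arms of 9 of 9 hairpins (miR-240-5p and miR-85-5p, minor arms, were earlier). A scaling that changes with the hour can move a midpoint, and midpoints were taken with TMM only. Total counts moved the median change over time in Alg1E by -0.27 log2. Exchanged libraries would break the order of hours, which the Alg1E libraries kept on the N2 curves (Spearman rho 0.989 across 13 libraries). When the hours of 10 Alg1E libraries were moved earlier by the let-7-5p lag, 3 miRNAs differed in time course from 11 N2 libraries, all 3 among the 55 that differed in the same libraries as labelled, as one shift of all hours would give; moving early Alg1E hours later left 135 against 138. The mean lag was 1.55 h for 4 early risers, let-7-5p among them, and 2.60 h for 5 late risers, a difference of 1.05 h (jackknife SE 0.612), and mean offsets on the N2 curves, leaving out 18 to 20 h where the start of the curves bounds them, were -2 h at 21 to 24 h, -4.08 h at 25 to 28 h and -0.85 h at 29 to 30 h. The lag was largest at 25 to 28 h in 5 of 6 placements (means from -4.43 to -2.88 h) but not with each miRNA centred on its genotype mean, which removes constant level differences (-2.08, -1.90 and -0.90 h). In each placement the mean lag was smaller at 29 to 30 h than at 25 to 28 h. Neither a later start by one fixed time nor steadily slower development would give that alone, but it rests on the last hours, near the end of the curves. A later start by one fixed time therefore cannot be told apart from slower development, and an effect of the genotype on timing may be either or neither.

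In Alg1A, 6 miRNAs had another time course than in N2 by edgeR. They are miR-60-5p (adjusted p = 0.0262 with edgeR, net change 0.71 log2 in Alg1A and -1.13 in N2), miR-355-5p (0.0262, 1.40 and 0.14), miR-8206-3p (0.0262, 3.19 and 0.71), miR-1020-3p (0.0262, 1.31 and 0.19), miR-4816-5p (0.0262, 1.66 and -0.42) and miR-255-3p (0.0262, 2.37 and -0.46), each over 13 hours. The neighbours in rank, miR-60-3p (adjusted p = 0.0743 with edgeR, 2.28 and 0.39) and miR-83-5p (0.0765, 1.70 and -0.03), did not pass. Of 100 splits of the 26 libraries, 6 gave as many calls, with 19 as the highest other count, so a chance split cannot be excluded.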

How the results depend on the processing

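TMM from major arms or from paired major arms, the moved Alg1E hours and the omission of the Alg1A libraries of 18 and 19 h were chosen after the data were seen. Of the alternatives for counts, offsets and medians, runs with an hour left out among them, 207 were labelled similar and 30 moved. A count was labelled similar if its total stayed within 1.5-fold, whatever its split into higher and lower. For Alg1E against N2, 88 higher and 94 lower thus passed as similar to 129 and 49 with TMM from paired major arms. An offset was labelled by direction and side of the threshold, not by size. The 207 therefore do not show that splits or offset sizes were kept. Of 1823 alternatives for 125 results on named miRNAs in 24 settings, with each hour left out counted apart, 1635 kept direction and side of the threshold, 168 lost the call, 10 gained one and 10 reversed. lin-4-5p (0.017, edgeR adjusted p = 0.887) and miR-48-5p (0.061, adjusted p = 0.677) turned above 0 in Alg1E against N2 with TMM from major arms. With TMM from paired major arms lin-4-5p (0.11), miR-48-5p (0.15) and miR-84-5p (0.078) did so against N2, and lin-4-5p (0.0079), miR-84-5p (0.016) and miR-237-5p (0.029) against Alg1A, none of them called by edgeR (adjusted p from 0.291 to 0.948). miR-237-3p over time in Alg1E lay above 0, with no call, with 2 spline df (adjusted p = 0.822 with edgeR) and with a straight line (0.819). Over all settings, lin-4-5p ranged from -0.53 to 0.11 in Alg1E against N2, miR-48-5p from -0.53 to 0.15, let-7-5p from -1.64 to -0.14 and miR-241-5p from -2.31 to -1.46.

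The 26 calls of Alg1A against N2 became 55 with a spline per genotype, 45 with only the 26 libraries compared, 54 without the Alg1A libraries of 18 and 19 h, and with fewer hours 14 (even), 4 (odd), 6 (18 to 23 h) and 14 (25 to 30 h). Over time, Alg1A went from 111 to 71 without those libraries, and Alg1E from 65 to 39 with 2 df and 128 with a line plus an 8 h wave. The 6 time courses of Alg1A became 11 with total counts and 14 with DESeq2, and limma-voom also gave 6, of which 5 were shared. With edgeR they became 0 with no filter (58 at an unadjusted p under 0.05), at a mean CPM of at least 10 (41), with 2 df (11), with a line (5) and without 18 and 19 h (17). The 86 of Alg1E became 18 with 2 df, 39 with a line and 3 with moved hours in 10 Alg1E and 11 N2 libraries, which gave 55 as labelled. fry called 12 lists in Alg1E against N2 and 11 against Alg1A where camera called 1; fry does not compare a list with other miRNAs. Apart from fewer libraries or hours, the cause was not tested.

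With each hour left out in turn (leave-one-out), the counts ranged from 23 to 35 for Alg1A against N2, 174 to 182 for Alg1E against N2, 182 to 193 between the mutants, 67 to 103 over time in N2, 88 to 116 in Alg1A, 48 to 72 in Alg1E, 64 to 108 for the time courses of Alg1E and 0 to 16 for those of Alg1A. The last was 16 by edgeR without 20 h, 1 without 19 or 22 h, and 0 without 18, 21, 23, 25 or 30 h (27 at an unadjusted p under 0.05 without 18 h). Low depth limits single arms such as miR-5592-5p and miR-85-5p, with 0 reads at some early hours.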

Other observations

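The tests of scaling and of mixed reads were chosen only after the result was seen.

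In 17 clusters of hairpins with a tested minor arm, 32 of 41 minor arms (78.0%) were higher in Alg1E than in N2, close to the 76.0% of all 96, and in 10 clusters every tested minor arm was. In the mir-35 to mir-41 cluster on II from 11537608 to 11538404 (+ strand), 5 of 5 tested minor arms were higher and 5 of 7 major arms lower. In the mir-54 to mir-56 cluster on X from 13144691 to 13145094 (- strand), 3 of 3 minor arms were higher and 2 of 3 major arms lower, and in the mir-73 to mir-75 cluster on X from 2368765 to 2372549 (+ strand) these were 3 of 3 and 3 of 3. In the cluster of mir-229 and mir-64 to mir-66 on III from 2172452 to 2173206 (+ strand), 2 of 4 minor arms were higher and 4 of 4 major arms lower. Other clusters went another way. mir-247 and mir-797 had 0 of 2 minor arms called higher by edgeR (0 at an unadjusted p under 0.05), mir-250 and mir-61 had 1 of 2, and no major arm was called lower in the cluster of mir-42 to mir-44 or that of mir-51 and mir-53. The counts for major arms rest on TMM, under which more of them were lower than with TMM from major arms (65 against 27 of 96). Clusters within 10 kb were formed after the values were seen.

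miR-46-5p, miR-47-5p, miR-63-5p, miR-230-5p, miR-65-3p and miR-66-3p were higher in Alg1A than in N2 and, with TMM, lower in Alg1E than in Alg1A. Of these 6, 5 were called lower in Alg1E with total counts (all but miR-47-5p), 2 with TMM from major arms (miR-63-5p and miR-230-5p) and 1 as a ratio to the major arm (miR-63-5p, -0.39, limma adjusted p = 0.0298). miR-47-5p was at 12.02% of its major arm in Alg1A and 12.90% in Alg1E. With TMM, miR-58a-5p, miR-82-5p, miR-83-5p, miR-45-5p, miR-2-5p, miR-49-5p, miR-60-5p, miR-61-5p and miR-788-3p were higher in Alg1A and higher still in Alg1E, and miR-254-5p was called in neither direction between the mutants. These groups were chosen after their values were seen. Across miRNAs, which are not independent replicates, the log2 changes of both mutants against the shared N2 libraries had r = 0.27, where unchanged mutants gave 0.49 in simulation. The covariance was 0.138 against 0.0186 in simulation, and 0.141 and 0.126 with the N2 libraries split by hour. Both mutants were called higher than N2 for 12 miRNAs (7.60 for independent lists, 0.01 in simulation) and lower for 3 (1.93 for independent lists, 0 in simulation by edgeR). With the N2 libraries split by hour, 2 and 8 were called higher in both and 0 and 0 lower by edgeR, so part of the overlap may come from the shared libraries or from the larger number of libraries.

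The higher minor arms in Alg1E were weighed against technical explanations. Scaling between libraries cancels within a hairpin, where the median log2 change was 2.05. With the share of reads without a feature in the model, the log2 minor arm share differed by 2.41 between Alg1E and N2 (SE 0.0545), against 2.35 without it, and without the 5 hairpins with most minor arm reads the share was 4.12 times that in N2, higher at 13 of 13 hours. If the libraries are taken as independent, a chance split can be excluded for the 182 calls of Alg1E against N2 (1 of 100 splits, highest other 158) and the 190 against Alg1A (1 of 100, highest other 137). The median was 0 calls over the other splits of each. A difference by genotype is the remaining hypothesis, and the labels give no batch that would separate it from the handling of the Alg1E libraries.

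The smaller increase of minor arms in Alg1A was weighed against reads from Alg1E libraries. The 26 calls of Alg1A against N2 exceeded those of other splits (1 of 100, highest other 17), so a chance split is unlikely if the libraries are taken as independent. Such splits cannot test a culture or batch shared by all libraries of a genotype. Mixed reads cannot raise the share of all miRNA reads above its sources, and by this share (total counts) 5 of the 16 minor arms called higher in Alg1A were called lower in Alg1E than in Alg1A, which argues against mixed reads for these 5 and leaves miR-47-5p and miR-254-5p open; the ratio to the major arm, called lower in Alg1E for 1 of the 16, does not exclude mixing for the other 4 by itself. For the arms higher still in Alg1E, the smallest share of mixed reads that would serve, 6.48%, needs a median change of 0.44 in the 38 minor arms at least 4-fold higher in Alg1E, and the median was 0.13 (SE 0.0708, bootstrap over the 38 arms as if independent), with 13 of 38 lower in Alg1A than in N2. These values come from TMM levels and not from shares of all miRNA reads, and the needed 0.44 carries no error, so the comparison is approximate. The first Alg1A libraries do not carry it, since 16 of 16 were called again without 18 and 19 h, and an effect of this genotype on single minor arms may remain, as a hypothesis.

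A hypothesis that minor arms, if short-lived, oscillate more over the larval cycle was tested with an 8 h wave in N2. edgeR called 20 of 96 minor and 14 of 96 major arms (exact two-sided sign test over hairpins with 1 arm called, p = 0.263), so the test decides nothing in N2. In Alg1E the counts were 33 and 17 (p = 0.00700 by the same exact test) and in Alg1A 14 and 17 (p = 0.629 by the same exact test). Minor arms held 8.15% of paired reads in Alg1E against 1.60% in N2, and more reads make calls easier. let-7-5p, which rose over these hours, was also called in N2 (edgeR adjusted p = 0.00646), so a call need not mean a repeated wave. The counts in Alg1E therefore do not show that minor arms oscillate more.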
